A study of Sus scrofa with 50 samples.

How the data were processed

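Gene expression was measured in Longissimus muscle, the long muscle of the back and loin, of 50 pigs of 2 breeds, the Basque pig, a local breed, and the Large White, a widely used commercial breed. Per the labels, muscle was frozen 30 minutes after slaughter from pigs of 145 kg live weight, RNA was extracted with Trizol, and 350 ng from each pig was labelled with Cy3. The other channel of every array held 1 reference, an equal-amount pool of the RNA of all 50 pigs, labelled with Cy5. Each pig was hybridised on 1 array. No dye swap, slide or scan date is given in the sources used here, so array batches could not be examined.

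The deposited values were taken as log2 ratios of the 2 channels, as the authors processed them. Per the submitters' processing notes limma was used, with no version or step named. Neither the log base nor the normalization is given in the sources used here. Base 2 was assumed because limma's log ratios have it. The array medians lay between -0.0109 and 0.00577, close to 0 on every array. The deposited table held 15197 probes, of which 3769 (24.8%) were empty on every array. The other 11428 probes were analysed. Among these, 0.965% of the cells were empty, each probe had at least 29 values, and each group had at least 3 values of each probe. The rule by which the authors emptied spots is not given in the sources used here.

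The channel in the numerator is not given in the sources used here. It was inferred from the values by a rule fixed before the data were examined. The pool is the arithmetic mean of the 50 RNAs, so in variable probes the mean over pigs of a log ratio of pig over pool lies below 0 (the mean of logs is below the log of the mean), and that of pool over pig lies above 0. The median mean log ratio was -0.170 in the 572 most variable probes (5%) and -0.00553 in the other probes, and the values were read as pig over pool. In an addition made after the data were examined, the mean of the unlogged ratios of a variable probe, which has to be 1 for pig over pool, had a median log2 of 0.0210, against 0.360 for the inverse ratios. For 86.9% of the 572 probes the unlogged ratio was nearer to 1 than its inverse. A pool that holds each of 50 pigs equally also limits pig over pool to 5.64 on the log2 scale. No value lay above that limit and 7 lay below its negative. Read as pool over pig, these 7 values would exceed the limit. At 1 probe 10 pigs had a median of -5.18, and as pool over pig they would together hold more than an equal pool contains. Both argue against pool over pig, provided the values keep the scale of the raw ratios. A planned check by skewness gave a median of -0.108 in the most variable probes, where a value above 0 was expected for pig over pool. Its sign also depends on how levels are distributed over the pigs. Pig over pool has an upper limit but no lower one, so low tails are possible and this check cannot decide. By default limma forms Cy5 over Cy3, which would be pool over pig here. The direction is therefore an inference that the labels do not settle. If it is the opposite, all directions below turn and the counts of called probes stay, but slopes on unlogged ratios change in size.

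Samples were grouped by the breed and rearing system in their titles, which gave 5 groups of 10 pigs: Basque pigs in conventional, alternative and extensive rearing and Large White pigs in conventional and alternative rearing. The design text calls the pigs of a group biological replicates. One model with a mean per group was fitted to every probe over all 50 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and 9 comparisons were taken from it. P-values were adjusted over the 11428 probes by the Benjamini-Hochberg method, and a probe was called at an adjusted p under 0.05. Standard errors and intervals come from this fit, and the number of arrays limits their precision. The fit was tested on simulated data for the comparison of alternative with conventional rearing in Basque pigs, with 200 of 11428 probes changed. Of the changed probes, 25.0% were called at a difference of 0.25 on the log2 scale, 73.1% at 0.5 and 96.7% at 1. All of those called had the right sign, and 3.89% of the calls were false. Noise was drawn independently for each probe and array, so these rates do not cover probes that vary together over the pigs.

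Correlations of differences across probes used the 8274 probes with a value on every array. Their p-values come from two-sided tests with 100000 permutations of the pigs between the groups of the first difference, and their SD from 100 bootstrap draws of the pigs within groups. Principal components were computed on the same probes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

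Gene names could not be given. Each probe's identifier is a sequence accession with a position, the deposited table does not pair it with a gene, and 0 of the identifiers were found in the gene tables used here. The rule fixed before the data were examined names, per comparison, the genes with the largest positive and negative difference among the called ones. It was kept for probes and shortened to the top 2 in each direction of the averaged breed comparison and of extensive against conventional rearing, with an identifier printed only for the first of each. The 28 gene lists fixed before the data were examined, and the averaging of probes by gene symbol, could not be applied for the same reason. Probes of 1 source sequence share an accession: the 11428 probes came from 10594 sequences, and 825 sequences had more than 1 probe.

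Alternatives chosen before the data were examined were centring each array on its median, quantile normalization between arrays, leaving out the probes with the smallest variance, array weights, a robust fit, a fit on the compared groups alone, the replicate number as a block, an adjusted p under 0.01 and leaving out each array in turn. Chosen afterwards were leaving out 3 arrays that stand apart, averaging probes of 1 sequence, the number of empty spots as a covariate, setting extensive pigs against the conventional and alternative Basque pigs together, and the alternatives for the correlations.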

Results

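Transcript levels in Longissimus muscle were compared between Basque and Large White pigs and between rearing systems. Conventional and alternative rearing were represented in both breeds and extensive rearing in Basque pigs alone, with 10 pigs in each of the 5 groups. Each pig's RNA was measured on 1 array against a common pool of all 50 RNAs, and every value below is a log2 ratio to that pool or a difference between such ratios, read as pig over pool. This direction was inferred from the values and is not stated in the labels. The default of limma points the other way, and 1 planned check gave a sign that was not expected but cannot decide the direction. If it is the opposite, higher and lower change places throughout. The arrays held between 10587 and 11424 values each, with SDs of the log ratios between 0.188 and 0.510 and single values between -6.82 and 3.38. Extensive Basque array 3 had the lowest SD (0.188) and conventional Large White array 8 the highest (0.510).

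The arrays separated first by breed. The first principal component held 18.9% of the variance and had means of -7.82 ± 5.18 (SD, n = 10) in conventional Basque, -7.09 ± 3.39 (n = 10) in alternative Basque and -15.4 ± 5.45 (n = 10) in extensive Basque pigs, against 14.9 ± 4.84 (n = 10) in conventional and 15.4 ± 4.68 (n = 10) in alternative Large White pigs. All 30 Basque pigs lay below all 20 Large White pigs on it. The third component held 7.34% and separated the extensive Basque pigs, between 3.75 and 23.2, from the other 20 Basque pigs, which lay between -15.1 and -0.723. On the first component conventional and alternative pigs overlapped in both breeds, from -15.7 to -0.318 and from -11.7 to -1.30 in Basque pigs and from 6.70 to 20.9 and from 3.28 to 20.05 in Large White pigs.

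**Figure D1:**
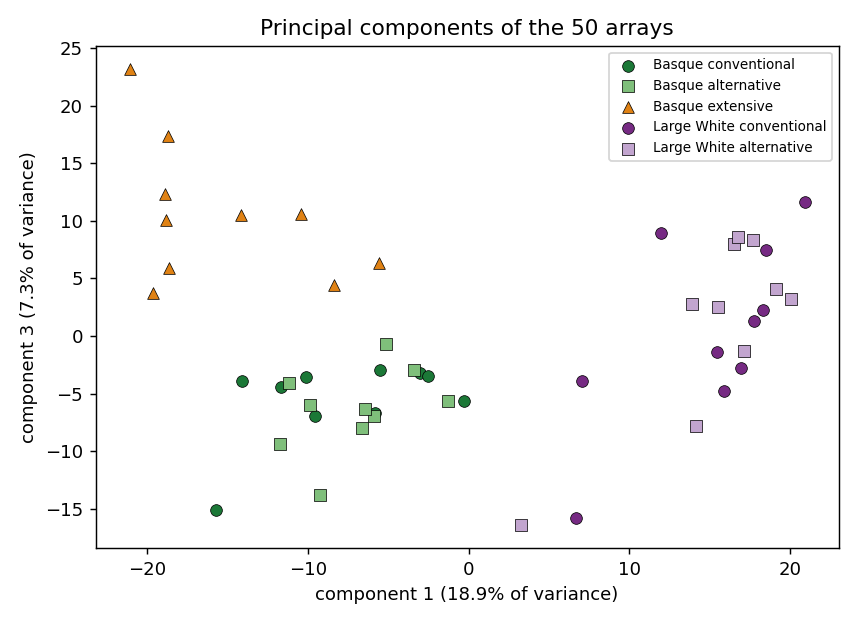
Scores of the 50 arrays on principal components 1 (x axis, 18.9% of the variance) and 3 (y axis, 7.34%), 1 point per pig, coloured by group. Basque pigs lie to the left of Large White pigs, and the extensive Basque pigs (3.75 to 23.2 on component 3) lie above the other Basque pigs.

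Breed was the first question of the design. Averaged over conventional and alternative rearing, 3841 of the 11428 probes (33.6%) differed between the breeds, 2032 higher and 1809 lower in Basque than in Large White pigs (limma, adjusted p under 0.05). Most differences were small: the median size among called probes was 0.29 on the log2 scale, or 1.22-fold, and 41 called probes were higher and 60 lower by over 1 on the log2 scale. The median half-width of the 95% interval of a difference was 0.14.

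The files do not pair the probes with genes, so probes are given by identifier. The largest difference upward was at probe BI339314.1_653, with 0.42 ± 0.29 (SD, n = 10) in conventional Basque and 0.40 ± 0.42 (n = 10) in alternative Basque pigs, against -1.18 ± 0.45 (n = 10) in conventional and -0.97 ± 0.43 (n = 10) in alternative Large White pigs. The averaged breed difference was 1.49 ± 0.11 (SE), or 2.81-fold (limma, adjusted p = 2.01e-14), and all 30 Basque pigs, extensive ones included, lay above the highest of the 20 Large White pigs. The next probe upward differed by 1.48 ± 0.27 (SE, limma, adjusted p = 3.84e-05). The Large White pigs varied widely at it, from -2.84 to 1.02, and 9 of 20 of them lay below -2, against 0 of 30 Basque pigs.

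The largest difference downward was at probe BQ598890.1_2149, with -1.79 ± 1.11 (SD, n = 10) in conventional and -1.58 ± 1.04 (n = 10) in alternative Basque pigs and 0.97 ± 0.53 (n = 10) and 0.97 ± 0.49 (n = 9) in the corresponding Large White groups. The difference was -2.66 ± 0.27 (SE), a 6.31-fold lower level in Basque pigs (limma, adjusted p = 1.37e-10). Of 30 Basque pigs, 27 lay below the lowest of 19 Large White pigs with a value. A second probe of the same sequence differed by -2.13 and followed the first over the arrays with r = 0.997. The next probe downward, at -2.30 ± 0.63 (SE, adjusted p = 0.00377), lay below -2 in 10 of 30 Basque pigs and in 0 of 20 Large White pigs.

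**Figure D2:**
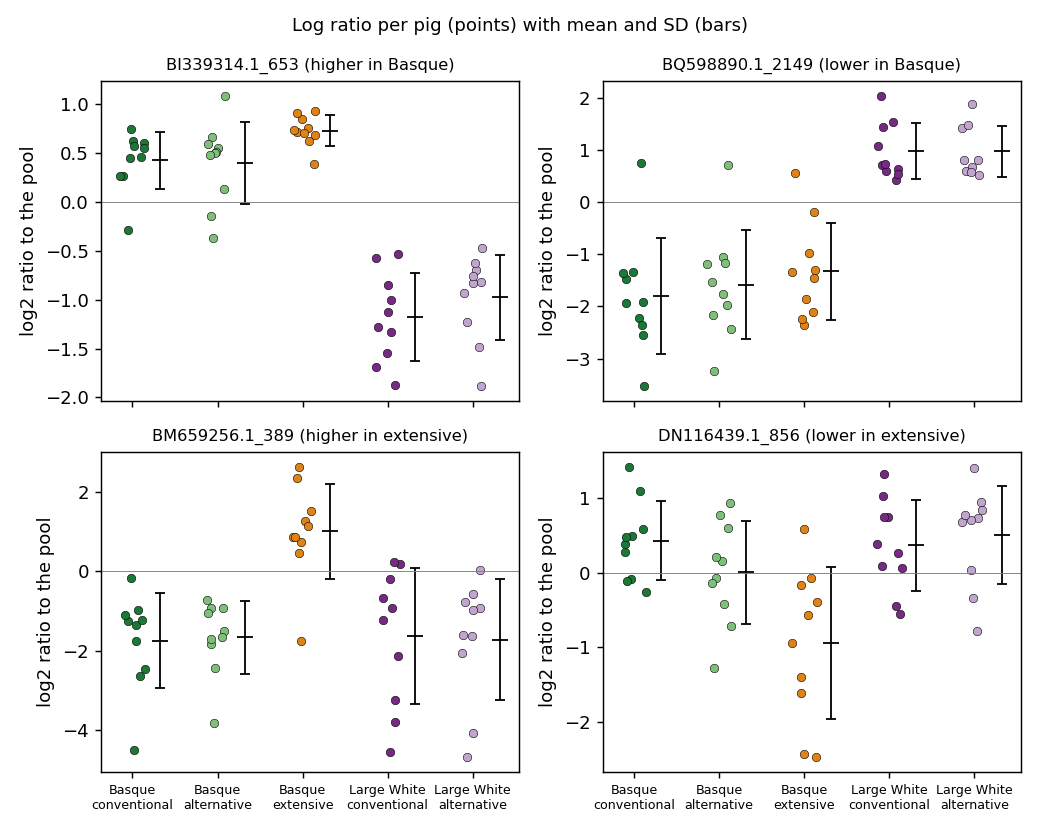
Log2 ratio to the pool (y axis) per pig (points) in the 5 groups (x axis), with mean and SD beside each group, for the probes with the largest called difference upward and downward by breed (top row) and in extensive against conventional Basque pigs (bottom row). At BI339314.1_653 all 30 Basque pigs lie above the 20 Large White pigs, and at BM659256.1_389 9 of 10 extensive pigs lie above all other Basque pigs.

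The breed difference was measured separately in each rearing system, on different pigs. In conventional rearing 1869 probes were called, 1042 higher and 827 lower in Basque pigs, and in alternative rearing 1939 were called, 980 higher and 959 lower. Of these, 587 were higher and 552 lower in both systems, where 89.4 and 69.4 were expected of independent lists, and 0 were called in opposite directions. Both lists come from 1 fit that shares each probe's estimate of the spread. This can raise an overlap above the expected number, here and in the overlaps below, and by how much was not tested. Among the 1869 probes called in conventional rearing, 98.6% had a difference of the same sign in alternative rearing. Across 8274 probes, which are not independent of each other, the differences in these systems correlated with Pearson's r = 0.834 ± 0.051 (bootstrap SD) and Spearman's rho = 0.784. The two-sided permutation p was 2.0e-05, or 8.0e-05 after Benjamini-Hochberg adjustment over 4 such correlations, and 95% of the permuted r values lay between -0.615 and 0.615. The test of the difference between the 2 breed differences, the breed by rearing interaction, called 0 probes (limma), with 259 at an unadjusted p under 0.05. Random divisions of the same pigs gave a median of 555, and 3 of 100 divisions, the real one included, gave as few. The interaction was measured less precisely than breed, with a median half-width of the 95% interval of 0.29, against 0.14 for the averaged breed difference. Its intervals excluded 1.5-fold or more for 79.8% of the probes and 2-fold or more for 96.3%. Interactions of 1.5-fold thus stay open at the remaining probes.

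**Figure D3:**
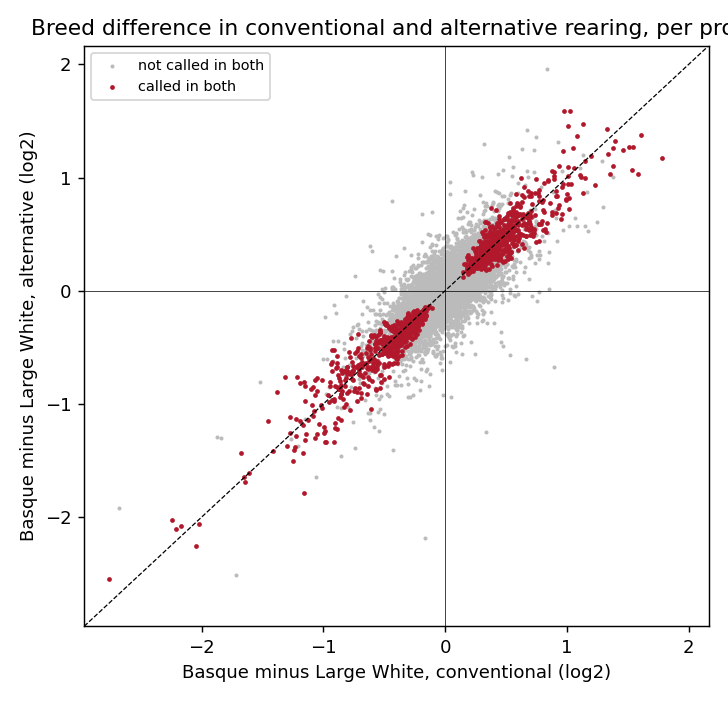
Basque minus Large White difference of each probe in conventional (x axis) and in alternative rearing (y axis), on the log2 scale, with the 1139 probes called in both systems in red and the line of equal differences dashed. The called probes lie along that line, and 0 of them have opposite signs.

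Alternative and conventional rearing were compared within both breeds. No probe was called in Basque pigs, in Large White pigs or in the average over the breeds (limma). At an unadjusted p under 0.05 there were 182 probes in Basque pigs, 538 in Large White pigs and 451 in the average, where random divisions of the same pigs gave medians of 380, 736 and 529. The smallest adjusted p was 1.00 in Basque and 0.719 in Large White pigs. The 95% intervals of the differences excluded changes of 1.5-fold or more for 93.4% of the probes in Basque and 92.0% in Large White pigs, and changes of 2-fold or more for 99.1% and 98.9%. No correlation between the differences of the breeds was detected across 8274 probes, with r = 0.0810 ± 0.0897 (bootstrap SD) and rho = 0.0867 (permutation p = 0.416, adjusted p = 0.671). Of the permuted r values 95% lay between -0.185 and 0.185, so a weaker correlation could have been missed.

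Extensive rearing, studied in Basque pigs, differed from both other systems. Against conventional rearing 414 probes were called (limma), 178 higher and 236 lower in extensive pigs, and against alternative rearing 514, of which 262 were higher and 252 lower. The median size of the called differences was 0.41 and 0.43 on the log2 scale, or 1.33-fold and 1.34-fold. Large differences were mostly upward: by over 1 on the log2 scale, 25 called probes were higher and 5 lower than in conventional rearing, and 36 higher and 3 lower than in alternative rearing.

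Probe BM659256.1_389 had the largest difference upward, from -1.75 ± 1.21 (SD, n = 10) in conventional and -1.66 ± 0.92 (n = 10) in alternative to 1.01 ± 1.20 (n = 10) in extensive Basque pigs. The difference from conventional pigs was 2.76 ± 0.58 (SE), or 6.76-fold (limma, adjusted p = 0.00416), and that from alternative pigs 2.67 ± 0.58 (SE, adjusted p = 0.00411). Its level in extensive pigs was above that of all 20 other Basque pigs in 9 of 10, and extensive pig 1 had -1.77. A second probe of the sequence differed by 2.65 between extensive and conventional pigs. The next probe upward rose by nearly the same amount, 2.75 ± 0.49 (SE, adjusted p = 8.99e-04), again with 9 of 10 extensive pigs above all other Basque pigs and pig 1 at -3.12. Both probes were also low in Large White pigs, with means of -1.63 ± 1.72 and -2.72 ± 0.82 (SD, n = 10) in conventional rearing.

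Downward, probe DN116439.1_856 had the largest difference from conventional pigs, with 0.43 ± 0.53 (SD, n = 10) in conventional and -0.95 ± 1.02 (n = 10) in extensive pigs, a difference of -1.38 ± 0.31 (SE, limma, adjusted p = 0.00697). Alternative pigs had 0.00414 ± 0.687 (SD, n = 10), and their difference from extensive pigs, -0.95 ± 0.31 (SE), did not pass (adjusted p = 0.0676). Of the 10 extensive pigs, 4 lay below all other Basque pigs. The next probe downward differed by -1.20 ± 0.19 (SE, adjusted p = 2.31e-04) from conventional and by -1.06 ± 0.19 (SE, adjusted p = 6.11e-04) from alternative pigs.

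Both comparisons of extensive pigs share those 10 pigs. They called 121 probes higher and 149 lower together, against 4.08 and 5.20 for independent lists, and 0 in opposite directions. The differences correlated across probes with r = 0.891, where unchanged groups that share 10 pigs gave 0.501 on average in 100 simulated draws (highest 0.720). The covariance was 0.0497 against 0.00911 in the draws, a difference of 0.0406. With the extensive pigs divided 5 and 5, so that no pig was shared, r was 0.637 on average over 100 divisions (0.538 to 0.712).

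Each Basque pig was also scored on the probes called between extensive and other Basque pigs when that pig was left out, with 0 for the mean of the other Basque pigs, 1 for the extensive mean and probes weighted by their precision. Extensive pigs scored 0.786 ± 0.319 (SD, n = 10) and the other Basque pigs 0.0910 ± 0.108 (n = 20), and all 10 extensive pigs lay above all 20 others. The weights were chosen after a score with all probes weighted equally had been seen, on which 9 of 10 extensive pigs lay above all others and pig 1 (0.221) within their range (-0.285 to 0.384). On the probes higher in extensive pigs alone, extensive pig 1 scored 0.228, within the range of the 20 others (-0.189 to 0.375), and on the lower probes extensive pig 3 scored 0.159, within their range of -0.0475 to 0.292.

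**Figure D4:**
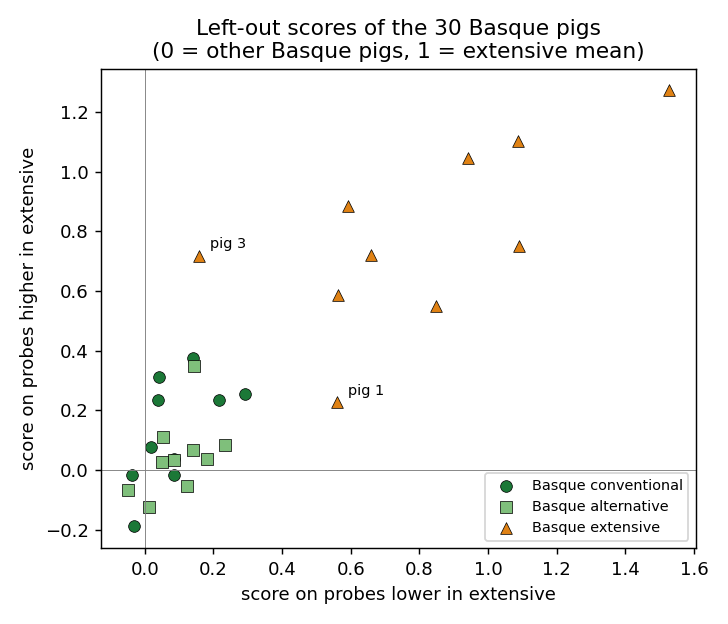
Left-out score of each of the 30 Basque pigs on the probes lower (x axis) and higher (y axis) in extensive pigs, where 0 is the mean of the other Basque pigs and 1 the extensive mean; points are pigs, coloured by rearing system. Extensive pigs lie toward the upper right, with pig 1 low on the higher probes (0.228) and pig 3 low on the lower probes (0.159).

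The counts for extensive rearing depended on the arrays and on the weight given to them. With array weights they were 826 against conventional and 933 against alternative rearing. Without extensive pig 7 they were 260 against conventional and 295 against alternative rearing, without pig 10 the latter was 316, and without the 3 arrays that stand apart (extensive Basque 3, conventional Large White 8 and alternative Large White 3) they rose to 740 and 793. The Large White arrays enter these counts only through the spread that all groups share. Leaving out conventional Large White 8 alone gave 489 and 594, and leaving out extensive Basque 3 alone gave 549 and 633. The balance of higher and lower probes against alternative rearing changed with these choices, from 262 and 252 to 438 and 495 with array weights, 343 and 450 without the 3 arrays, 276 and 357 without extensive pig 3 and 80 and 55 at an adjusted p under 0.01. With the number of empty spots per array as a covariate, which had a median of 57.5 in extensive, 29 in conventional and 20 in alternative Basque pigs, the count against alternative rearing was 329 and that against conventional rearing 399.

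Extensive and breed differences were compared across all probes, on a scale between the breeds and among called probes. No correlation was detected across probes. Extensive minus conventional and the breed difference in alternative rearing, which share no pig, had r = -0.0406 ± 0.0608 (bootstrap SD) and rho = -0.0473 (permutation p = 0.693, adjusted p = 0.693) across probes. Extensive minus alternative and the breed difference in conventional rearing had r = 0.0733 ± 0.0701 and rho = 0.0677 (permutation p = 0.503, adjusted p = 0.671). Pigs were also projected on the breed difference of the alternative pigs, with the projected conventional Large White mean at 0 and the conventional Basque mean at 1. Extensive pigs lay at 0.960 ± 0.138 (SD, n = 10) and conventional Basque pigs at 1 ± 0.120 (n = 10), a difference of -0.0398 (permutation p = 0.501). On the breed difference of the conventional pigs, with the alternative Large White mean at 0 and the alternative Basque mean at 1, extensive pigs lay at 1.07 ± 0.141 (n = 10) and alternative Basque pigs at 1 ± 0.116 (n = 10), a difference of 0.0748 (permutation p = 0.211). Of the probes called between extensive and conventional rearing, 34 were called in the same and 49 in the opposite direction by breed in alternative rearing, where 35.1 and 35.2 were expected of independent lists. Of those called between extensive and alternative rearing, 66 were called in the same and 28 in the opposite direction by breed in conventional rearing, where 42.1 and 41.9 were expected. These lists thus lean in different directions, and neither excess was tested. On the first principal component, which was computed with the extensive pigs included, their mean (-15.4) lay further from Large White pigs than those of conventional (-7.82) and alternative Basque pigs (-7.09).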

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

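The tests of explanations in this part were all chosen after the values had been seen. Within each group of 10, the highest and lowest pig were tested for a gap to the others by Dixon's criterion, in 65 combinations of a measure and a group. In 12 of them a pig stood apart, where chance gives about 1 in 20 for independent measures with normally distributed values. Counts of empty spots and probes picked for large differences are not such measures, so the 12 do not show an excess.

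Extensive Basque pig 1 lay at -1.77 at BM659256.1_389 and at -3.12 at the next probe upward, with the nearest extensive pig at 0.460 and 0.153, and on all probes higher in extensive pigs its left-out score of 0.228 was below the other 9 (0.549 to 1.27) and within the range of the 20 other Basque pigs (highest 0.375). A poor array is argued against by 10 empty spots, against 12 to 841 on the other 9 arrays, and by a spread around the group mean of 0.197, within their 0.170 to 0.236, and a swap is argued against because none of the 20 possible partners scored above 0.375. The first test of a wrong system label for this pig alone, a score over all probes with equal weights, did not argue against it (0.221, others -0.285 to 0.384), and a test on the lower probes with weights by precision was then chosen, since the low values at higher probes are the pattern itself. It argues against a wrong label, with 0.559 for pig 1 and at most 0.292 for the 20 others, as does left-out component 3 (3.65 against at most -0.630), but with equal weights the lower probes set pig 1 apart narrowly (0.452 against at most 0.426). A difference between single pigs may remain, and no biological explanation was tested because the labels name nothing that sets pig 1 apart.

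Extensive Basque array 3 had an SD of the log ratios of 0.188, with the nearest of its group at 0.319. Its slope against the mean of the other 9 extensive arrays was 0.222, and theirs were 0.595 to 1.23. The array correlated better with the other extensive arrays (r = 0.299) than with any other group (highest 0.0139), which argues against a pig of another group. A dilution of the pig's RNA with RNA of the pool, or of other pigs, could give small ratios and would give equal slopes on the unlogged scale for low and high probes. The slope was 0.191 on the low and 0.839 on the high side, a gap of 0.647 within those of the other 9 arrays (-0.641 to 2.87), and with the ratio turned the gap was -0.489 (others -0.626 to 5.11), so dilution and another compression of the ratios cannot be told apart with slopes this variable. Other technical causes were not tested, and no biological explanation was tested.

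Conventional Basque array 10 had 698 empty spots, with the next of its group at 300, and a value of -15.1 on the third principal component, with the next at -6.98. Alternative Large White array 10 had 410 empty spots, with the next at 194. Conventional Large White pig 8 lay at 35.5 on the second component (next 10.4) and alternative Large White pig 3 at 3.28 on the first (next 13.9). After removal of group means these arrays, pigs 8 and 3, had the highest correlation of any pair (r = 0.551). At BI339314.1_653 conventional Basque pig 5 lay at -0.285 (next 0.259), and at the next probe upward by breed conventional Basque pig 7 lay at -1.14 (next -0.200). At BQ598890.1_2149 conventional Basque pig 2 lay at 0.746 (next -1.34), within the range of the Large White pigs. At the next probe downward in extensive pigs, alternative Basque pig 1 lay at -0.928 (next -0.123).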

How the results depend on the processing

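The breed counts stayed within 1.5 times of the reported ones under 9 of 11 alternatives for the averaged comparison (3525 to 4186) and under 10 of 11 in conventional (1309 to 2313) and in alternative rearing (1406 to 2279). The interaction and the 3 comparisons of alternative with conventional rearing gave 0 probes under all 11. The counts for extensive rearing stayed within 1.5 times under 7 of 12 alternatives against conventional (344 to 604) and 7 of 11 against alternative rearing (388 to 703). Without the probes of below-median variance, where fewer were tested, there were 2427 averaged breed calls and 275 calls of extensive against conventional rearing. At an adjusted p under 0.01 the counts were 2499, 879 and 1002 for breed (averaged, conventional, alternative) and 119 and 135 for extensive against conventional and alternative rearing. Array weights gave 826 and 933 for these, leaving out the 3 arrays that stand apart 740 and 793, and the number of empty spots as a covariate 329 for the latter, with 318 of its 514 calls among them; the cause was not tested. Extensive against both other systems together, with 20 pigs in place of 10, gave 967. The last 3 alternatives and the averaging of probes of 1 sequence were chosen after the data were examined.

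With 1 array left out in turn, the counts ran from 3674 to 3981 (breed averaged), 1511 to 2046 (conventional), 1649 to 2097 (alternative), 260 to 549 (extensive against conventional) and 295 to 633 (against alternative). They stayed at 0 for the interaction and for alternative against conventional rearing averaged and in Basque, and ran from 0 to 1 in Large White pigs, with the 1 probe called without conventional pig 8. The lowest extensive counts came without extensive pig 7 and the highest without pig 3. The 8 probes described kept direction and call in 48 of 48 values under 6 alternatives. These were centring, quantile normalization, the robust fit, the replicate block, leaving out the 3 arrays that stand apart and the empty-spot covariate. The probes had been picked for the largest called differences, so this says little about the other calls.

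Replicate numbers are shared by the groups, and the values gave little sign that they pair the pigs. Across groups, pigs with the same number correlated by 0.00975 on average and pigs with different numbers by -0.000786. Of the pairs with the same number, 24 of 100 were above 0.1, and 7 of 50 pigs correlated best with a pig of their own number. Pairing was not tested, so a weak one stays open. With the replicate number as a block the counts were 3762, 1853 and 1885 for breed, 417 and 518 for extensive rearing and 0 for the others, so the block moved no count by over 1.5 times.

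For the direction of the ratio, the median absolute deviation in place of the variance gave -0.153 for the -0.165 between variable and other probes. The planned test by skewness gave a median of -0.108 in the most variable probes, where a value above 0 was expected for pig over pool, and the cause was not tested. Skewness also depends on how levels are distributed over the pigs, so it cannot decide the direction. The 4 correlations kept their sign without the probes of below-median variance and under quantile normalization, but the latter moved those of extensive with breed differences from -0.0406 to -0.0986 and from 0.0733 to 0.0140; the cause was not tested. Centring the arrays cannot move them. Gene lists and averaging by gene symbol were not run because no probe had a gene name, so each probe was its own row from the start. Signal over background is not given in the sources used here.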

Other observations

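The tests of single spots, of breed at low probes and of spread were chosen after the values had been seen; the random divisions and the test of arrays with many empty spots were planned before. Some probes were far below the pool in part of the pigs and near it in the rest. Values below -2 occurred 771 times at 268 probes, and 55 probes had them in at least 4 pigs. The cut of -2 does not show separate levels at each of these. The median of the other pigs was 0.520 at 1 of them but -1.28 at another. At BQ598890.1_2149 10 of 30 Basque pigs lay below -2, while 27 lay below the lowest Large White pig. Of these 55, 14 were low in Basque pigs alone and 7 in Large White pigs alone. The number of low pigs differed between the breeds at 10 of them after adjustment (Fisher's exact test, two-sided, Benjamini-Hochberg over 55), 5 low more often in Basque and 5 in Large White pigs.

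Single failed spots are argued against where a second probe of the sequence exists, at 95 of the low values from 20 sequences. The second probe was below -1 on the same array in 84.2% of these, with a median of -2.04. A pair with both probes below -2 was counted from each of them, which raises this share. The 5 arrays with the most empty spots held 9.48% of the low values of the 55 probes, about their share of the arrays. An empty spot cannot show a low value, so this share does not decide on poor arrays. Conventional Large White array 8, with 197 empty spots, was not among the 5. It had the most values below -2 of any array (54 of 771) and the largest spread around its group mean (0.336). Of the 10 breed-dependent probes 8 were low in 1 breed alone and 2 in both, and without the extensive pigs, with 20 Basque pigs in place of 30, 2 of the 10 passed the adjusted threshold. What separates low from other pigs was not tested. A sequence variant under both probes of a sequence stays open, since no genotype or probe sequence was used here.

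The division of pigs into groups was compared with random divisions of the same pigs, 100 per comparison with the real one included. Chance is argued against for breed averaged (3841 probes, highest other 8), in conventional (1869, highest other 101) and in alternative rearing (1939, highest other 14). The same holds for extensive against conventional (414, highest other 36) and alternative rearing (514, highest other 48). For each of these 1 of 100 divisions, the real one, gave as many, the smallest share that 100 divisions can give. Such divisions cannot tell breed or rearing from an array batch that follows the groups. For the interaction and the 3 comparisons of alternative with conventional rearing, which called 0 probes, all 100 gave as many, with highest counts of 3 (interaction), 2 (averaged), 3 (Basque) and 51 (Large White). A structure among the Large White pigs other than the rearing system would give such a count as 51, but this was the highest of 99 divisions and no such structure was tested.

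Conventional and alternative Basque pigs differed at fewer probes than most random divisions of the same 20 pigs, and few probes were also seen for the interaction. The 182 Basque probes at an unadjusted p under 0.05 compare with a median of 380 in the other 99 divisions (173 to 909), and 2 of 100 divisions, the real one included, gave as few. For the interaction (259 probes, median of the others 555) 3 of 100 gave as few, for the average over breeds (451) 32 and in Large White pigs (538) 27.

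The spread of a pig's values around its group mean, as a median absolute deviation, was 0.225 ± 0.0389 (SD, n = 20) in Large White and 0.196 ± 0.0298 (n = 20) in conventional and alternative Basque pigs, a difference of 0.0290 (two-sided permutation test within rearing systems, p = 0.0115). Extensive pigs, which have no Large White counterpart and were left out of this test, had 0.209 ± 0.0201 (n = 10), between these values. Without conventional Large White pig 8 and alternative Large White pig 3 the difference was 0.0196 (same test, p = 0.0409). The group means around which the spread was taken still included these pigs, so their influence was removed only in part.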
